A study of Rattus norvegicus with 6 samples.

How the data were processed

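Total RNA from magnetically separated basal and non-basal cell fractions of the rat epididymis (Sprague-Dawley, 48 days of age) was labelled with biotin and hybridised to Affymetrix RaGene 2.0 ST arrays, 3 per fraction. The deposited values are log2 expression values that the authors made by RMA (background correction, quantile normalization and summary of probes into probe sets) in Affymetrix Expression Console, per the submitters' processing notes. The software version, the probe set library and the genome build behind the probe sets were not given in the sources used here. That the scale is log2 was checked on the values, which ranged from 1.46 to 14.33 with array medians of 6.63 to 6.70. Because RMA forces the probe distributions to match, a difference that moved most genes the same way would be removed from these values. The summary of probes on this scale also compresses differences of very dim and very bright probe sets.

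Groups and replicate numbers were taken from the sample titles, and every array had its own column. The labels name 3 rats and triplicate experiments but do not tie an array to an animal. The p-values therefore measure only the spread between these samples, which may be technical. No pair of arrays held the same data, since the SD of the differences within a fraction was at least 0.301.

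Probe sets were named through the platform annotation, in which 18511 of the 36685 probe sets carried 1 gene symbol, 575 carried several and 17599 were unnamed. For 18394 named probe sets the Entrez identifier was found in the RefSeq gene table of the GRCr8 assembly, which was used for names only, and 0 symbols changed. Probe sets with several symbols or none were left out of the tests by gene. Where a gene had several probe sets (291 genes), the one with the highest mean over the 6 arrays was used, which gave 18166 genes. No gene was called in opposite directions by different probe sets, and 35 were called by some of their probe sets only. Coordinates were left out because the build of the array annotation was not named, and no reference sequence was used here. No filter on dim probe sets was applied.

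Log2 differences, basal minus non-basal, were fitted for each gene with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a replicate block, with 4 residual degrees of freedom before moderation. Tests were two-sided. The p-values were adjusted over all 18166 genes by the Benjamini-Hochberg method, and genes at an adjusted p under 0.05 were called higher or lower. Standard errors are the moderated ones of limma, and SDs are over the 3 arrays of a fraction. The 24 gene lists held markers of epididymal cell types, of other cells that a magnetic fraction could hold, and pathways of this epithelium. Of their 609 distinct symbols 547 were measured. Each list with at least 5 measured members was tested against the other genes with camera at a preset correlation between genes of 0.01, adjusted over the 24 lists. The correlation estimated from these data was used beside it, and with it none of the 24 lists passed. The fry test, which asks whether the genes of a list move on balance one way, was run as well. The tests, the lists, the check genes and the rule for named genes were fixed before the data were examined.

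Named genes were the 12 with the highest and the 12 with the lowest log2 difference among genes at an adjusted p under 0.05 whose fractions did not overlap, leaving out unnamed loci, small RNA genes and olfactory and vomeronasal receptors. To these came up to 4 members of each list with the smallest p, past the threshold or not, and the check genes. Members named as exceptions within a list, Lama2, Nid1 and Col4a1 among the basement membrane genes, and the genes of the 10 lists added later were chosen after their values were seen.

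Alternatives were the replicate number as a block, quantile normalization between arrays, centring of each array on its median, filters at a group mean of 5 or 7, an intensity trend with robust spread, array weights, the mean of all probe sets of a gene, all probe sets in place of named genes, other thresholds, and each array left out in turn. Leaving out basal replicate 3 and non-basal replicate 1 together was added after the data were seen. Medians over all genes were 0.00343 as deposited, -0.0292 after quantile normalization and -0.0114 after centring. Random lists numbered 10000 and bootstrap intervals used 10000 draws. The draws were of genes, so the intervals measure the spread between genes and not between arrays.

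The procedure was tested on simulated values for 18166 genes with 3 against 3 arrays. For changes of 0.5, 1, 2 and 3 on the log2 scale, 50 genes of each size were changed, and 30%, 82%, 100% and 98% of them were called. In the same simulation 8 unchanged genes were called, 4.91% of all calls, and 0 genes were called where nothing had been changed. The simulated noise was independent between genes, whereas the estimated correlation within the real lists reached 0.89, so these rates may not carry over. A simulated admixture of 15%, made without noise, was recovered as 15. That value was bound to come out, so it checks the arithmetic and not the accuracy of a share. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.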

Results

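Transcript levels were measured in cell fractions of the epididymis, the long coiled duct in which sperm mature after leaving the testis. The tissue came from Sprague-Dawley rats aged 48 days and was divided by a magnetic method into a basal cell fraction and a non-basal fraction. Basal cells are small epithelial cells that sit on the basement membrane of the duct, beneath the tall principal cells that face the lumen. Each fraction was hybridised to 3 Affymetrix RaGene 2.0 ST arrays, giving 6 arrays and 36685 probe sets in log2 RMA units, of which 18166 genes could be named and tested. The labels do not say whether each array held RNA of 1 rat or of several, nor which surface molecule the separation used. Array medians lay between 6.63 and 6.70, so the 6 distributions were closely matched, and the number of arrays sets the precision. Correlations across probe sets were 0.982 to 0.988 among basal arrays, 0.985 to 0.991 among non-basal arrays and 0.956 to 0.974 between the fractions.

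The comparison asked which genes differ in expression between basal cells and the other cells of the rat epididymis. The basal fraction was richer in transcripts of epithelial basal layer genes, among them the laminin chain Lamb3, the keratins Krt14 and Krt15 and the transcription factor Tp63. Cadherins, desmosomal genes and connexins, tested as 1 list, were higher. The non-basal fraction was richer in transcripts of fibroblasts, smooth muscle, blood vessels and lymphocytes, with the matrix proteoglycan gene Lum lowest in the basal fraction at a log2 difference of -4.75. Secretory genes of the luminal epithelium had smaller differences, and most of them did not pass the test. Because the fractions differed in transcripts of several cell types, a pathway gene called below need not differ within any cell type. The list tests behind these statements used a preset correlation between genes. With an estimated correlation 0 of the 24 lists passed after adjustment, the lowest adjusted p being 0.187, and 4 lay at an unadjusted p under 0.05.

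With limma and Benjamini-Hochberg adjustment, 1401 genes were higher and 1297 were lower in the basal fraction, together 14.9% of the genes tested. At least 2-fold differences were found for 415 of the higher and 645 of the lower genes, and at least 8-fold differences for 9 and 68. In all 2698 of these genes the 3 basal values lay on one side of the 3 non-basal values. With 3 arrays per fraction, passing the threshold almost requires such separation, so this count is no added evidence. Such separation was seen in 32.9% of all genes, where chance gives 10%. The first principal component held 76.7% of the variance and parted the fractions, with basal replicate 3 at -21.1 against -45.7 and -43.4 for the other basal arrays. Non-basal replicate 1 stood apart on the second component, which held 10.5%, at -27.1 against 14.6 and 10.8. The counts depended on single arrays: 560 genes were higher and 631 lower without basal replicate 1, 509 and 578 without basal replicate 2, 624 and 637 without non-basal replicate 2, and 527 and 542 without non-basal replicate 3. Leaving out basal replicate 3 and non-basal replicate 1 together, an alternative chosen after seeing the data, gave 2499 and 2124.

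Of the genes fixed beforehand as checks of the separation, the epithelial basal markers were higher in the basal fraction. Itga6, the laminin-binding integrin subunit of hemidesmosomes, averaged 10.85 ± 0.363 (SD, n = 3) in the basal and 8.77 ± 0.248 (n = 3) in the non-basal fraction, a log2 difference of 2.08 ± 0.213 (SE; limma adjusted p = 0.0034). Tp63, the basal cell transcription factor, averaged 10.19 ± 0.0999 against 7.09 ± 0.545, a difference of 3.10 ± 0.266 (adjusted p = 0.00247). Krt14 and Krt15, keratins of basal layers, were higher by 3.40 ± 0.543 and 3.32 ± 0.333, with adjusted p of 0.0118 and 0.00325. The Krt14 call was lost without basal replicate 1 or 2, where the adjusted p reached 0.0663. Keratin genes have close copies, so the assignment of signal to Krt14 or Krt15 is uncertain. Cldn1, a claudin found around epididymal basal cells, was higher by 1.90 ± 0.242 (adjusted p = 0.00573). The labels do not name the surface molecule of the separation. Had it been the product of Itga6, Cldn1 or another check gene, the higher value of that gene could follow from the selection and would be no check. Ptprc, the common leukocyte antigen, was lower by a log2 difference of -1.98 ± 0.365 (adjusted p = 0.0189), a call that held in 2 of the 6 fits with 1 array left out and had an adjusted p of 0.0914 without non-basal replicate 3. Col1a1, a chain of type I collagen, was lower at -4.04 ± 0.669 (adjusted p = 0.0131), a call that held in 3 of those 6 fits, with an adjusted p of 0.0738 without non-basal replicate 3.

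The check genes of the luminal epithelium did not pass the test. Lcn5, the epididymal retinoic acid-binding lipocalin, averaged 13.53 ± 0.274 in the basal and 13.85 ± 0.0848 in the non-basal fraction, with a difference of -0.32 ± 0.145 (limma adjusted p = 0.204). Adam7, a membrane protein of principal cells, had a difference of -0.64 ± 0.291 (adjusted p = 0.204), Crisp1, a secreted sperm-coating protein, -0.79 ± 0.234 (adjusted p = 0.0787), and the water channel gene Aqp9 -0.66 ± 0.321 (adjusted p = 0.231). Basal replicate 3 carried the highest basal values of all 4. Without it the limma adjusted p fell to 0.00863 for Adam7, 0.0208 for Lcn5 and 0.0438 for Aqp9. Without non-basal replicate 1 that of Crisp1 was 0.0408. For the clear cell genes Atp6v1b1 and Foxi1 the differences were -0.04 (adjusted p = 0.929) and 0.18 (adjusted p = 0.517), and for the macrophage gene Cd68 the difference was -0.08 (adjusted p = 0.836). The sign for Atp6v1b1 and Cd68 changed when single arrays were left out. Krt5, Acta2 and Pecam1 were not analysed here.

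**Figure D1:**
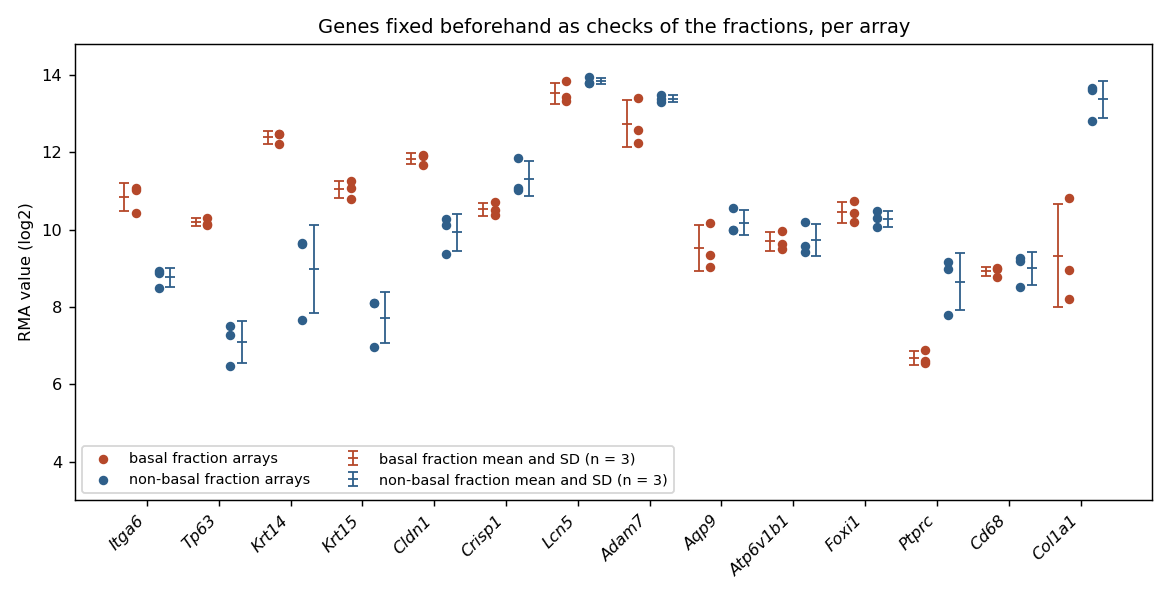
RMA values (log2, vertical axis) of the 14 check genes on each of the 3 basal (red) and 3 non-basal (blue) arrays, with points for arrays and bars for the mean and SD of each fraction. Itga6, Tp63, Krt14, Krt15 and Cldn1 lie higher in the basal fraction and Ptprc and Col1a1 lie lower, while Lcn5 averages 13.53 and 13.85 in the basal and non-basal fractions.

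Among the 12 genes with the highest differences, Lamb3, the beta chain of laminin-332, was 12.6-fold higher (log2 difference 3.66 ± 0.462, limma adjusted p = 0.00568), and Itga2, a collagen-binding integrin subunit, was 7.50-fold higher (2.91 ± 0.311, adjusted p = 0.00374). Serpinb5, which encodes maspin, was 9.41-fold higher, the sodium pump regulator Fxyd3 9.12-fold, and Nrg1, a ligand of ErbB receptors, 8.40-fold. Rnf39, Anxa8, Ankrd22 and the transporter gene Slc16a12 were higher by 3.11, 3.06, 2.96 and 2.95 on the log2 scale, besides Tp63, Krt14 and Krt15 above. The 12 genes with the most negative differences were led by Lum, which was 26.9-fold lower in the basal fraction (-4.75 ± 0.529, adjusted p = 0.0042), by Dpt, which encodes dermatopontin, 22.6-fold lower (-4.50 ± 0.553, adjusted p = 0.00535), and by the complement gene C7, 22.3-fold lower (-4.48 ± 0.692, adjusted p = 0.0106). Mfap5, Igsf10, Col1a1, Col1a2, Dcn, Col14a1 and the growth factor gene Igf1 had differences between -4.24 and -3.89. The remaining genes of this set were Gzmf, a granzyme of cytotoxic lymphocytes, at -4.02 ± 0.398 and Cd7, a surface protein of T and natural killer cells, at -3.91 ± 0.412. Granzyme genes have near-identical copies in the rat, so the call for Gzmf itself is uncertain. When non-basal replicate 3 was left out, the adjusted p of C7, Col1a1, Col1a2, Dcn and Col14a1 rose to 0.0642, 0.0738, 0.0705, 0.0846 and 0.0613, and the calls of all 5 were also lost without basal replicate 2.

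Of the 23 measured basal epithelial markers, 21 were higher, 1 was lower and 1 did not pass, with a median log2 difference of 2.08 and the same counts when adjusted over the list alone. The list was higher by camera (adjusted p = 7.35e-14), but the adjusted p was 0.372 with an estimated correlation. The smallest p-values belonged to Jag2, a Notch ligand (2.27 ± 0.0699, limma adjusted p = 0.000908), the integrin subunit Itgb4 (2.82 ± 0.176), Trim29 (1.56 ± 0.118) and Igfbp2 (2.17 ± 0.169). The exceptions were Ngfr, the low-affinity neurotrophin receptor, lower at -1.31 (adjusted p = 0.00637), and the glycerol and water channel gene Aqp3 at -0.34 (adjusted p = 0.218). With 1 array left out, 16 to 21 members were higher. The mean deviation of the list from each gene's overall mean was 1.09, 1.05 and 0.711 in basal replicates 1 to 3 and -1.34, -0.761 and -0.746 in non-basal replicates 1 to 3. Of these 23 genes, 19 belong to another list too.

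In the list of cadherins, desmosomal genes and connexins, 14 of 22 members were higher, 1 was lower and 7 did not pass, and 16 were higher when adjusted over the list alone. The list was higher by camera (adjusted p = 4.95e-08), with an adjusted p of 0.187 with an estimated correlation. The desmosomal plaque genes Pkp3 and Pkp1 were higher by 1.61 ± 0.0791 and 2.85 ± 0.209, the placental cadherin gene Cdh3 by 2.81 ± 0.254, and Ctnna1, which links cadherins to actin, by 0.72 ± 0.0553. The member that was lower was the neural cadherin gene Cdh2, at -0.81 (limma adjusted p = 0.0218, reaching 0.0997 without non-basal replicate 3). Among 26 basement membrane and hemidesmosome genes, 13 were higher, 9 lower and 4 did not pass (15 and 9 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.139). Without basal replicate 1 or 2, 8 were higher and 7 lower. Itgb4, Agrn and Itga3 were higher by 2.82, 2.02 and 2.09, whereas the laminin chain gene Lamc3 was lower at -1.62 ± 0.126. The type IV collagen gene Col4a1, the laminin chain gene Lama2 and the nidogen gene Nid1 were also lower, at -1.80, -3.80 and -2.71. Of the 26 genes of this list, 7 belong to another list. Tight junction genes went both ways, with 8 of 33 higher, 3 lower and 22 not passing (10 and 3 adjusted over the list alone, camera adjusted p = 0.139). Cldn4 and the polarity gene Pard3 were higher by 1.08 ± 0.13 and 0.50 ± 0.0577, and Jam3 and Cldn11 were lower at -1.44 ± 0.139 and -2.38 ± 0.288. Without non-basal replicate 1 the tight junction list was higher, at a camera adjusted p of 0.0135 and with 14 members higher, whereas 3 were higher without basal replicate 1, basal replicate 2 or non-basal replicate 3 and 4 without non-basal replicate 2.

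**Figure D2:**
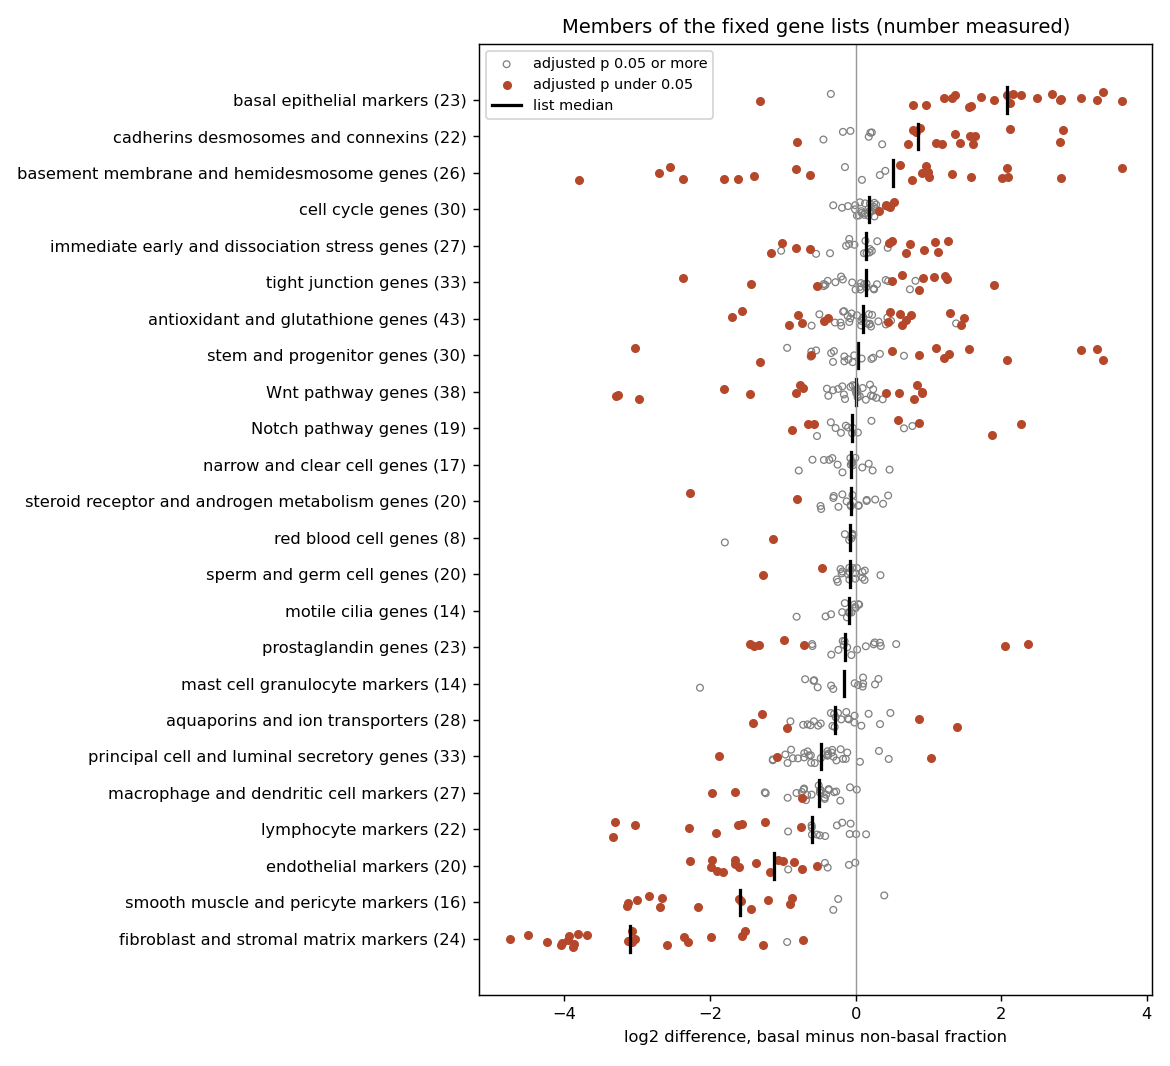
Log2 differences, basal minus non-basal (horizontal axis), of each measured member of the 24 gene lists fixed beforehand (vertical axis, number measured in brackets), with filled points for members at an adjusted p under 0.05 and a bar at each list median. Medians run from 2.08 for basal epithelial markers to -3.10 for fibroblast and stromal matrix markers.

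Few luminal epithelial genes passed the test. Of 33 genes of principal cells and luminal secretion, 1 was higher, 2 were lower and 30 did not pass, with a median log2 difference of -0.48. Adjusted over the list alone, 1 was higher and 9 were lower, and 16 lay at an unadjusted p under 0.05. The list was lower by camera (adjusted p = 0.000187), a call with an adjusted p of 0.533 with an estimated correlation, 0.141 with fry and 0.0541 without basal replicate 1. The scaffold gene Akap12 was lower at -1.88 ± 0.113 (limma adjusted p = 0.00176) and Spag11a, a beta-defensin-like secreted protein, at -1.08 ± 0.223 (adjusted p = 0.0267). Etv4, an ETS transcription factor, was higher by 1.04 ± 0.229 (adjusted p = 0.0334). The calls of Spag11a and Etv4 each held in 1 of the 6 fits with 1 array left out. Clu, which encodes clusterin, averaged 13.52 ± 0.0594 and 13.78 ± 0.0647 in the basal and non-basal fractions (adjusted p = 0.0537). The mean deviation of the list was -0.668 and -0.292 in basal replicates 1 and 2 but 0.225 in basal replicate 3, which lay between the 0.454 of non-basal replicate 1 and the 0.145 and 0.135 of the other non-basal arrays. Without basal replicate 3, 12 of the 33 genes were lower, and 4 without non-basal replicate 1, whereas 1 was lower without any other array. None of 17 narrow and clear cell genes passed in limma, and 0 lay at an unadjusted p under 0.05 (camera adjusted p = 0.383). Among these were Rhcg at -0.78 ± 0.341, Atp6v1g3 at -0.59 ± 0.286, Bsnd at -0.44 ± 0.186 and Atp6ap2 at 0.23 ± 0.108. Rhcg passed without basal replicate 3 (adjusted p = 0.0113), as did Atp6ap2 (adjusted p = 0.0366).

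Stromal and vascular genes were lower in the basal fraction as groups. Of 24 fibroblast and stromal matrix markers 23 were lower and 1 did not pass, over all genes and adjusted over the list alone, with a median of -3.10 (camera adjusted p = 1.42e-16, and an adjusted p of 0.372 with an estimated correlation). Fibronectin (Fn1), matrix Gla protein (Mgp), Sparc and periostin (Postn) had differences of -2.36 ± 0.139, -3.13 ± 0.301, -1.52 ± 0.155 and -3.68 ± 0.4. Of 16 smooth muscle and pericyte markers 13 were lower and 3 did not pass (15 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.85e-11, and an adjusted p of 0.269 with an estimated correlation). The muscle coactivator gene Myocd was lower at -1.21 ± 0.082, Abcc9 at -1.61 ± 0.119, Tagln at -1.58 ± 0.134 and the pericyte gene Rgs5 by 8.02-fold. Of 20 endothelial markers 15 were lower and 5 did not pass (17 lower adjusted over the list alone; camera adjusted p = 1.29e-12, and an adjusted p of 0.187 with an estimated correlation). Tie1, Emcn, Erg and Plvap were lower at -1.60 ± 0.0967, -1.98 ± 0.146, -1.99 ± 0.163 and -1.66 ± 0.142. Basal replicate 3 was the basal array with the highest values of all 3 lists. Its mean deviation for fibroblast markers was -0.746, against -2.04 and -1.73 in the other basal arrays, for smooth muscle markers -0.471 against -1.08 and -1.01, and for endothelial markers -0.41 against -0.664 and -0.682. With 1 array left out, the number of fibroblast markers that were lower ranged from 11, without basal replicate 2 or non-basal replicate 3, and 13, without non-basal replicate 2, to 23, and that of endothelial markers from 10, without basal replicate 2, to 15.

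Of 22 lymphocyte markers 9 were lower and 13 did not pass (13 lower adjusted over the list alone), with a median of -0.60 (camera adjusted p = 4.75e-07, and an adjusted p of 0.462 with an estimated correlation). Prf1, which encodes perforin, was lower at -3.33 ± 0.303 (limma adjusted p = 0.00266), the cytotoxic granule genes Nkg7 and Gzma at -3.30 ± 0.346 and -3.03 ± 0.379, and the kinase gene Zap70 at -0.75 ± 0.106. Of 27 macrophage and dendritic cell markers 3 were lower and 24 did not pass, with a median of -0.51 and the same count adjusted over the list alone. The list was lower by camera (adjusted p = 0.000187), with an adjusted p of 0.555 with an estimated correlation and 0.197 with fry. The 3 were Ptprc, Laptm5 (-1.66 ± 0.32) and the cathepsin gene Ctss (-0.73 ± 0.144). Tyrobp had a difference of -1.23 ± 0.372 (adjusted p = 0.0826). Non-basal replicate 1 carried less macrophage signal than the other non-basal arrays, with a mean deviation of -0.365 against 0.747 and 0.589, while basal replicates 1 to 3 lay at -0.413, -0.0319 and -0.526. Without non-basal replicate 1, 17 of the macrophage and 14 of the lymphocyte markers were lower. Without non-basal replicate 3 the numbers were 0 and 4, without non-basal replicate 2 they were 0 and 5, without basal replicate 1 0 and 4, and without basal replicate 2 1 and 4. Of the macrophage markers 1 was lower without basal replicate 3. Without non-basal replicate 3, the adjusted p of Laptm5 and Ctss was 0.102 for each. None of 14 mast cell and granulocyte markers passed in limma, although 6 lay at an unadjusted p under 0.05 (camera adjusted p = 0.258) and 5 were lower without non-basal replicate 1. Among these, Kit differed by -0.34 ± 0.0856, Tpsab1 by -0.52 ± 0.136, Tpsb2 by -0.57 ± 0.185 and Hdc by -0.69 ± 0.23.

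**Figure D3:**
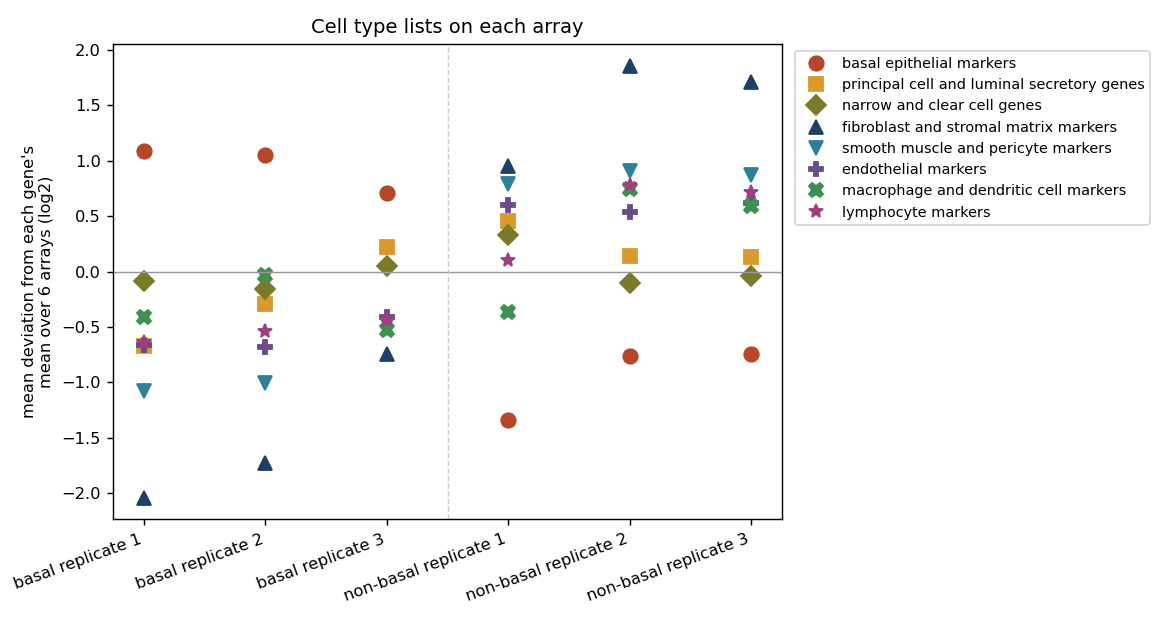
Mean deviation of the members of 8 cell type lists from each gene's mean over the 6 arrays (log2, vertical axis) on each array (horizontal axis), with 1 symbol per list. Fibroblast markers stand at -0.746 in basal replicate 3 against -2.04 and -1.73 in the other basal arrays, and macrophage markers at -0.365 in non-basal replicate 1 against 0.747 and 0.589 in the other non-basal arrays.

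Genes of other cells and structures of the duct gave few calls. Of 20 sperm and germ cell genes 2 were lower (camera adjusted p = 0.267), namely Smcp at -1.27 ± 0.256 and Ddx4 at -0.46 ± 0.103, both also when adjusted over the list alone. Odf2 and Akap4 differed by 0.34 ± 0.0983 and -0.24 ± 0.106 and did not pass. Of 8 red blood cell genes 1 was lower, Hbb-b1 at -1.13 ± 0.244 (camera adjusted p = 0.139), while Hba-a1 differed by -1.80 ± 0.525 (limma adjusted p = 0.0761). Globin genes have near-identical copies, and without non-basal replicate 1 the list was lower (camera adjusted p = 0.0198). Without non-basal replicate 3 the adjusted p of Smcp, Ddx4 and Hbb-b1 was 0.104, 0.13 and 0.118. None of 14 motile cilia genes passed in limma, and 1 lay at an unadjusted p under 0.05 (camera adjusted p = 0.139), although 2 were lower without basal replicate 3. Their differences included Drc1 at -0.81 ± 0.241 and Hydin at -0.41 ± 0.173.

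Among 30 stem and progenitor genes 10 were higher, 3 lower and 17 did not pass (11 and 5 adjusted over the list alone), with a median of 0.032 (camera adjusted p = 0.247; fry, which does not compare the list with other genes, adjusted p = 0.00793). Without basal replicate 1 or 2, 5 were higher and 2 lower, and 6 were higher without non-basal replicate 3. The members with the smallest p were Trim29, Tp63, Krt15 and Itga6, all higher, and 17 of the 30 genes belong to another list. Notch pathway genes went both ways, with 4 of 19 higher and 3 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.926; fry adjusted p = 0.00915, higher). With 1 array left out 3 to 5 were higher and 1, without basal replicate 1, basal replicate 2 or non-basal replicate 2, to 5, without basal replicate 3, were lower. The ligand genes Jag2, Dll1 and Jag1 were higher by 2.27 ± 0.0699, 1.87 ± 0.161 and 0.87 ± 0.11, and the receptor gene Notch3 was lower at -0.87 ± 0.0787. Notch3 is also on the smooth muscle and pericyte list, which was lower, and 5 of the 19 Notch genes belong to another list. The median of the Notch list was -0.0471 and its mean 0.185, so their signs differ. Of 38 Wnt pathway genes 6 were higher and 8 lower (8 and 9 adjusted over the list alone; camera adjusted p = 0.654). Without basal replicate 2, non-basal replicate 2 or non-basal replicate 3 the counts fell to 3 and 3, and without basal replicate 1 to 3 and 4. Fzd6, Wnt4 and Wnt6 were higher by 0.91 ± 0.096, 0.81 ± 0.0935 and 0.91 ± 0.109, and Fzd4 was lower at -0.72 ± 0.078. The median of the Wnt list was 0.00143, opposite in sign to its mean of -0.279 and to the direction of the test. Cell cycle genes were higher as a list (camera adjusted p = 0.0012, and an adjusted p of 0.187 with an estimated correlation), by small amounts. Of 30 members 5 were higher, none lower, and the median was 0.18, with the same counts adjusted over the list alone. Without basal replicate 1, basal replicate 2 or non-basal replicate 2 the count was 1, without non-basal replicate 3 it was 2 and without non-basal replicate 1 it was 3. Mcm2, Mcm7, Foxm1 and Ccna2 were higher by 0.52 ± 0.0705, 0.45 ± 0.0759, 0.41 ± 0.0863 and 0.47 ± 0.106. Only Mcm2 passed in each of the 6 fits with 1 array left out, and without basal replicate 2 the limma adjusted p of the other three reached 0.0663, 0.106 and 0.134.

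In the lists of prostaglandin, antioxidant and immediate early genes most members did not pass, and those that did went both ways. Of 23 prostaglandin genes 2 were higher, 5 lower and 16 did not pass (3 and 5 adjusted over the list alone; camera adjusted p = 0.283; fry adjusted p = 0.0177, lower). Of the lower genes 2 passed without basal replicate 1 or non-basal replicate 3 and 3 without basal replicate 2 or non-basal replicate 2. The constitutive cyclooxygenase gene Ptgs1 was 4.14-fold higher in the basal fraction (2.05 ± 0.212, limma adjusted p = 0.00352) and the prostaglandin transporter gene Slco2a1 5.19-fold higher (2.37 ± 0.175, adjusted p = 0.00206). The inducible cyclooxygenase gene Ptgs2 was 1.98-fold lower (-0.98 ± 0.0666, adjusted p = 0.00197) at high levels in both fractions, 12.41 and 13.39, and the phospholipase gene Pla2g4a was lower at -1.33 ± 0.117. Of 43 antioxidant and glutathione genes 9 were higher and 7 lower (10 and 8 adjusted over the list alone; camera adjusted p = 0.483). The counts were 3 and 2 without non-basal replicate 3, 4 and 3 without basal replicate 2, 4 and 4 without basal replicate 1, and 6 and 3 without non-basal replicate 2. Gstp1 and Gclc, of glutathione conjugation and synthesis, were higher by 1.45 ± 0.0992 and 0.77 ± 0.0695, and the secreted enzymes Gpx3 and Sod3 were lower at -1.56 ± 0.0829 and -1.70 ± 0.149. Immediate early and dissociation stress genes were high in both fractions, with median levels of 11.88 and 11.21, and 8 of 27 were higher and 4 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.139). Hspb1 and Dusp5 were higher by 1.10 ± 0.0812 and 1.13 ± 0.109, and Nr4a2 and Nr4a3 were lower at -1.02 ± 0.074 and -0.82 ± 0.0914. Without non-basal replicate 2 this list was higher, at a camera adjusted p of 0.04, and 2 members were lower without basal replicate 1, basal replicate 2, non-basal replicate 2 or non-basal replicate 3.

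Of 28 aquaporin and ion transporter genes 2 were higher and 3 lower, over all genes and adjusted over the list alone, and with 1 array left out 1 to 2 were higher and 2 to 4 lower. The list was lower by camera (adjusted p = 0.0348), a call with an adjusted p of 0.519 with an estimated correlation, 0.127 with fry, 0.119 without basal replicate 1 and 0.142 without non-basal replicate 1. Aqp1, a water channel of vessels and efferent ducts, was lower at -1.41 ± 0.15, the chloride channel gene Ano1 at -1.29 ± 0.189 and Car14 at -0.94 ± 0.147, and the sodium channel subunit gene Scnn1g was higher by 1.40 ± 0.164. The adjusted p of Ano1 was 0.0551 without non-basal replicate 3 and that of Car14 0.0543 without basal replicate 1. Of 20 steroid receptor and androgen metabolism genes 2 were lower and 18 did not pass, and 1 was lower adjusted over the list alone (camera adjusted p = 0.195; fry adjusted p = 0.032, lower). Hsd11b1, which regenerates active glucocorticoid, was lower at -2.27 ± 0.32 (limma adjusted p = 0.00781, and 0.0523 without non-basal replicate 3), and the oestrogen receptor gene Esr1 at -0.80 ± 0.199 (adjusted p = 0.047, and up to 0.158 without basal replicate 1). Without non-basal replicate 3 none of this list was lower, and without non-basal replicate 1, 2 were higher. Ncoa1 and Hsd17b10 differed by -0.30 ± 0.0794 and 0.45 ± 0.132 and did not pass.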

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

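The alternatives were planned before the data were examined, except that leaving out basal replicate 3 and non-basal replicate 1 together was chosen afterwards. Of the 1401 higher and 1297 lower genes, 1400 and 1297 were also called with array weights, which called 2868 and 2323, and the pair of arrays left out together gave 2499 and 2124, both settings giving less or no weight to the arrays that stood apart. With 1 array left out, 509 (without basal replicate 2) to 2068 (without basal replicate 3) genes were higher and 542 (without non-basal replicate 3) to 1607 (without non-basal replicate 1) lower, with 3 to 4 lists higher and 5 to 7 lower. A stricter adjusted p of 0.01 left 491 and 556 genes, a 2-fold minimum 415 and 645, and an unadjusted p with a 2-fold minimum 427 and 702, as these thresholds are built to do. Quantile normalization, centring, both filters on dim genes, a trend in the spread, averaged probe sets and all probe sets gave 1214 to 1599 higher and 1286 to 1479 lower. Camera with an estimated correlation called 0 lists higher and 0 lower, where camera with the preset correlation called 3 and 7. Fry called 5 higher and 6 lower, losing the principal cell (adjusted p = 0.141), macrophage (0.197) and aquaporin (0.127) lists and gaining the stem (0.00793), Notch (0.00915), prostaglandin (0.0177) and steroid (0.032) lists.

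No pairing of the arrays by replicate number was seen. Deviations of same-numbered arrays from their fraction means correlated at 0.0052, -0.0113 and 0.0014, and no array correlated best with its own number. Arrays that stood apart could hide a shared animal, so pairing is not excluded. With the replicate number as a block, 982 genes were higher and 1027 lower, of which 911 and 961 were called without it, with 3 lists higher and 7 lower.

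Of 123 named genes 95 were called, and 74 of these passed under every alternative run on single genes. The other 21 lost the call somewhere, mostly with 1 array left out, and none changed sign. Calls lost numbered 14 to 18 without basal replicate 1 or 2 or non-basal replicate 2 or 3. They numbered 3 without basal replicate 3 and 6 without non-basal replicate 1, in fits of equal size. Most named genes were chosen for a large difference or a small p, so these shares do not stand for all calls. Without basal replicate 2, 501 of all 1401 higher and 573 of all 1297 lower genes kept the call. Of 28 named genes not called, 18 passed under some alternative. Signs changed for Hemgn (-0.186 to 0.0519 with 1 array left out, the latter without non-basal replicate 3), Atp6v1b1 (-0.194 to 0.193 with 1 array left out, 0.0668 of them without basal replicate 2, 0.0234 with array weights and 0.0555 with both arrays left out) and Cd68 (-0.317 to 0.0636 with 1 array left out, 0.0224 of them without non-basal replicate 3), none of them called. The cause was not tested. The narrow and clear cell list changed direction without non-basal replicate 1 (adjusted p = 0.96, and as low as 0.174 with another array left out). The Notch list changed direction with the block (adjusted p = 0.954), after quantile normalization (0.89), after centring (0.954), with the stricter dim filter (0.726), without non-basal replicate 2 (0.996, where other left-out arrays gave 0.714 or more) and with fry, its median and mean having opposite signs. The aquaporin list lost its call after quantile normalization (0.0757), with both dim filters (0.0507 and 0.15) and with array weights (0.0625). Low signal limits dim genes, whose log2 differences are compressed.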

Other observations

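The gene lists in the first 2 paragraphs, and the killer cell and T cell lists of the last, were drawn up after the genes of the report had been seen. Their tests therefore describe these data only, and their p-values were adjusted over the 10 added lists. Of 16 measured genes of the ErbB system, the receptors and ligands of the epidermal growth factor family, 6 were higher in the basal fraction, 0 lower and 10 did not pass, with a median of 0.196 (camera adjusted p = 0.011, and an adjusted p of 0.405 with an estimated correlation), and the highest camera adjusted p with 1 array left out was 0.0338, without non-basal replicate 2. Besides Nrg1, the receptor gene Egfr was higher by 2.49 and the ligand genes Epgn, Tgfa and Hbegf by 2.41, 2.29 and 2.17, each called by limma in all 6 fits with 1 array left out. The sixth was Areg, higher by 0.60 (limma adjusted p = 0.0497), which passed in 1 of those fits. Of 47 keratin genes 11 were higher and 0 lower (camera adjusted p = 0.0104, and an adjusted p of 0.405 with an estimated correlation), with Krt7 and Krt80 higher by 2.55 and 2.38. The counts of higher keratins ranged from 4, without basal replicate 2, to 11, with 5 without basal replicate 1, 6 without non-basal replicate 2 and 7 without non-basal replicate 3. Integrins went both ways, with 5 of 22 higher and 6 lower (camera adjusted p = 0.495), or 11 lower without non-basal replicate 1. The epithelial subunits Itga2, Itga3, Itga6, Itgb4 and Itgb6 were higher by 2.91, 2.09, 2.08, 2.82 and 2.42, and Itga5, Itga7 and Itga8 were among the lower ones at -1.84, -0.89 and -1.76.

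In the TGF beta and BMP pathway 12 of 34 genes were lower and 2 higher (camera adjusted p = 0.0104, and an adjusted p of 0.405 with an estimated correlation). Chrdl1, Tgfb3 and Bmp4 were lower at -3.53, -1.97 and -1.96, while the ligand gene Bmp7 was higher by 1.32. The number of lower genes ranged from 6, without non-basal replicate 3, to 16, without non-basal replicate 1, and that of higher genes was 4 without basal replicate 3 or non-basal replicate 1 and 1 without any other array. Retinoid genes also went both ways, without a call for the list (7 of 20 higher, 2 lower, camera adjusted p = 0.495), and with 2 higher and 1 lower without basal replicate 1 or 2 and 3 higher without non-basal replicate 3. The retinoic acid-making enzyme gene Aldh1a2 was lower at -2.82, and Dhrs3, which returns retinal to retinol, and the retinoic acid-degrading enzyme gene Cyp26b1 were higher by 1.34 and 0.52, all called with any 1 array left out. Lrat, which stores retinol as esters, was higher by 1.83 (limma adjusted p = 0.0301, and 0.119 without basal replicate 2). Clade B serpins (2 of 18 higher, 1 lower, camera adjusted p = 0.775) and Schwann cell markers (1 of 12 higher, 1 lower, camera adjusted p = 0.175) did not pass as lists. With 1 array left out 1 to 3 of these serpins were higher and 1 to 2 lower, and 0 to 1 of the Schwann cell markers higher and 1 to 3 lower. Of 62 other beta-defensin, WFDC, PATE and SPINK family genes 2 were higher, 2 lower and 58 did not pass, with a median of -0.40 (camera adjusted p = 0.00152, lower; 0.566 with an estimated correlation and 0.212 with fry). Of these genes 4 were lower without basal replicate 3 or non-basal replicate 1, whereas 1 was higher and 1 lower without any other array. Of 17599 unnamed probe sets 606 were higher and 286 lower, 5.07%.

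The tests on bright probe sets, on an even admixture and on a shift of the whole array in the paragraphs that follow were chosen after the results they measure had been seen. The tests on carry-over and on stromal admixture were also aimed at patterns already seen in these data. The difference between the fractions called 2698 genes, and the other ways of splitting the 6 arrays into 3 and 3 called at most 0 by limma at the same threshold. At an unadjusted p under 0.05 the real split called 5443 genes and the others at most 1040. There are 10 such splits and 1, the real one, gave as many genes, which are too few splits for a share under 0.05. Each other split also mixes the fractions, which widens the spread within its groups, so its count is no measure of chance.

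Secretory genes of the duct lumen had a median difference of -0.478, whereas fibroblast genes had a median of -3.10. A carry-over of luminal RNA or cells into the basal fraction, in amounts that vary between preparations, could add to this: the 26 of the beta-defensin, WFDC, PATE and SPINK family genes above with a mean of at least 9 had a median 0.41 higher in basal replicate 3 than in basal replicate 1, at percentile 100 of 10000 random lists matched on level (-0.207 to 0.0179 for the central 95%). These 26 genes varied more among the non-basal arrays, where such a carry-over cannot act, with a median 0.801 higher in non-basal replicate 1 than in non-basal replicate 2 by a comparison chosen afterwards (percentile 100; -0.0743 to 0.154 for random lists), whereas the mean deviation of the secretory list itself spanned -0.668 to 0.225 among basal and 0.135 to 0.454 among non-basal arrays, so the test leaves open whether carry-over, variation between animals or expression by the basal cells lies behind the difference. Bright probe sets near the top of the scale may hide part of the difference. Without regard to sign, the dimmer members of the secretory list differed by a median of 0.749 and the brighter by 0.387, a gap of 0.362 (bootstrap interval 0.0163 to 0.607). Even the dimmer members differed far less than the fibroblast genes, so brightness alone would leave most of that contrast unaccounted for. It is not known whether secretory genes should differ as much as fibroblast genes.

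Basal replicate 3 lay nearer the non-basal arrays than the other basal arrays did. Whether the whole array was shifted cannot be told here: its median difference from the other basal arrays was -0.013 over all genes, but RMA matches the arrays, so a value near 0 was bound to come out. An even admixture of the whole non-basal fraction matched the lymphocyte genes, which gave a share of 6.51% (interval 5.55 to 16.3), and the fibroblast genes, 8.41% (6.81 to 13.2), but not the secretory genes: starting from the other basal arrays, that share predicts them -0.629 from the non-basal mean (-0.584 at the upper bound), and they lay at -0.0119 (-0.221 to 0.196). For 4 macrophage genes the share was -12.9% (-23.2 to -3.74), or -1.35% (-2.91 to 1.38) against basal replicate 1 and -29.9% against basal replicate 2. These genes cannot decide, because their share depends on the baseline array. The macrophage list of non-basal replicate 1 also lay within the range of the basal arrays, at a mean deviation of -0.365. An admixture of stromal tissue stays open, as fibroblast, smooth muscle and endothelial genes gave overlapping shares of 8.41%, 14.3% (9.25 to 16) and 12.2% (7.85 to 16.8). These came from the 23, 11 and 12 members past a minimum gap of 1 log2 unit. Shares above 0 were bound to come out, since this array had the highest basal values of these lists, so only their overlap was open. The intervals hold the spread between genes of 1 array, and single fibroblast genes gave -11.5% to 91.6%. The secretory excess of this array may then have a separate source, or the animals may differ, which was not tested.

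Cytotoxic granule genes such as Prf1 and Nkg7 were far lower in the basal fraction, whereas Cd3d, Cd3e and Cd3g differed by -0.26, -0.53 and -0.60 and did not pass. Natural killer or other innate cytotoxic cells in the non-basal fraction are a possible explanation. A list of 16 killer cell genes outside the fixed list was drawn up after the granule genes had been seen, so its test is no independent support. These genes had a median of -0.713 (camera adjusted p = 0.000104, and an adjusted p of 0.405 with an estimated correlation), with 7 lower and 0 higher. Of these, Il12rb2 at -1.66 was called with any 1 array left out, and the number of lower genes ranged from 1, without basal replicate 2 or either of non-basal replicates 2 and 3, to 9, without non-basal replicate 1. The 14 T cell genes outside the fixed list had a median of -0.394 (camera adjusted p = 0.0234, and 0.0717 without non-basal replicate 3; 0.566 with an estimated correlation), with Cd28 lower at -1.74 and Bcl11b higher by 1.31 (6 genes lower without non-basal replicate 1, but 0 without basal replicate 1 or 2), so T cells are not excluded. The CD3 genes lay near the bottom of the scale, where differences are compressed, and killer receptor genes have close copies.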
